A study of Mus musculus with 24 samples.

How the data were processed

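CUT&RUN, in which a nuclease tethered to an antibody releases the DNA around the bound protein for sequencing, was run on a mouse embryonic fibroblast line that carries doxycycline-inducible Mef2c, Gata4 and Tbx5 and an eGFP reporter of Myh6. Per the labels, 300000 cells were plated per well and transfected with siControl, siJunb or siH1f0, 1 µg/mL doxycycline was added the next day, and cells were collected at day 1 of induction, with about 250000 cells per condition. Ground-state cells were not reprogrammed. The labels list 24 samples, and 16 of them entered the work through 1 peak list each. They were MEF2C at day 1 under siControl (n = 2), siJunb (n = 3) and siH1f0 (n = 3), and H1.0 and H3K9me3 in the ground state (n = 2 each) and under siControl at day 1 (n = 2 each). The other 8 samples, IgG controls, were not analysed here, and neither were measurements of Junb or H1f0 RNA or protein, so the knockdowns were not checked.

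Per the submitters' processing notes, reads were processed with Bowtie2 and SEACR on the mouse build mm10, with versions not given in the sources used here. Whether the IgG samples set the peak threshold, and how duplicates and fragment sizes were handled, was likewise not given in the sources used here. Each deposited list came from 1 sample and carries SEACR's relaxed setting in its name. The deposited values are signal, that is whole-number coverage summed over each peak and its maximum within the peak, and no scaling to depth or to a spike-in showed in the values. These peak scores are the authors', and they were used to describe, rank or filter peaks within a list. They were compared between lists only in the tests of why H1.0 lists differed in length and in the weighing of weaker enrichment under siJunb. The labels give 30 M reads per sample, and the number aligned was not given in the sources used here, so precision was judged from list length and from the spread between samples.

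Peaks on chromosomes 1 to 19, X and Y were used. No further filter for repeat-rich or artefact-prone regions was applied here. Overlapping or touching peaks of the 8 MEF2C lists were merged into 77240 union regions with a median width of 1951 bp, and a library held a region when at least 1 bp of a peak lay in it. Coordinates are 1-based on mm10. Gene positions came from a RefSeq table of GRCm38.p6, the assembly of mm10, with 49943 genes in use, 21887 of them protein-coding. That table gave neither strand nor exons, so a region counted as next to a gene when it lay within 5 kb of either annotated gene end, in place of the start site named in the design, and exons, introns and untranslated regions were not told apart. The genome sequence was not used here, so the intended searches for MEF2 and AP-1 motifs were not run.

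A MEF2C region was called gained under a knockdown when all libraries of the knockdown and no siControl library held it, and lost when both siControl libraries and no library of the knockdown held it. The same count was taken in all 10 splits of the libraries into groups of the same sizes, and in 100 randomised tables that kept the number of regions per library and of libraries per region. Region numbers, covered lengths and shares of regions held were compared between groups with exact permutation tests, two-sided. Their smallest possible p was 0.2 for 3 against 2 libraries, 0.1 for 3 against 3 and 0.333 for 2 against 2. No such test could therefore pass 0.05. Gene lists and odds for marked and unmarked regions were tested with Fisher's exact test across genes or regions, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Positions of lost regions were tested with the same test across regions, without adjustment. Genes and regions are not replicates, and neighbours can share a region, so these p-values describe the pooled lists and not the spread between cultures. Overlap between kinds of region was set against 100 random circular shifts within chromosomes, or 20 for pairs of single lists. Mean changes over gene families have 95% bootstrap intervals from 1000 draws of 5 Mb blocks of the genome, which cover the choice of genes within 1 pair of libraries. Labels call the samples biological replicates without saying what was repeated, so p-values measure the spread between these samples, which may be partly technical.

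The 21 gene lists (sarcomere and contractile, cardiac transcription factors and natriuretic genes, cardiac calcium handling and ion channels, cardiac energy metabolism, fibroblast and extracellular matrix, AP-1 family, linker histones, smooth muscle, skeletal muscle, neuronal, hepatocyte, blood and immune, endothelial, cell cycle, housekeeping, olfactory receptors, vomeronasal receptors, zinc finger proteins, Hox genes, clustered protocadherins and ribosomal proteins) were fixed before the data were examined. The last 6 were defined by symbol prefix, so Rps also took the Rps6 kinases and Zfp also took the Zfpm genes. Genes to be named were fixed by a rule at the same time. It took, for each knockdown, the 10 gained and 10 lost regions with the highest median within-list percentile of maximum signal, with the nearest protein-coding gene. It took every member of the cardiac, fibroblast, AP-1 and linker histone lists with a gained or lost region within 5 kb, up to 10 per list. It always took Junb, H1f0, Mef2c, Gata4, Tbx5, Myh6, Nppa, Actc1, Tnnt2, Ttn, Ryr2, Jun, Fos, Fosl1, Col1a1, Postn and Thy1, and for H1.0 and H3K9me3 the 10 protein-coding genes per direction with the largest change in gene body covered by both libraries of a state. Ties were ordered by gene length. Further genes are named as members of a list beside its count, or are said to be chosen after their values were seen.

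The deposited names fall into 2 naming series, 7 lists whose names begin with M, here the first naming series, and 9 others, here the second. The first held MEF2C siControl replicate 1, siJunb replicate 1 and siH1f0 replicate 3, replicate 1 of H1.0 and of H3K9me3 in the ground state, and H1.0 replicate 2 and H3K9me3 replicate 1 at day 1. The labels do not say what the names stand for, and the series were treated as a possible technical batch. Alternatives were lists of equal length (11731 peaks, the shortest MEF2C list), equal covered length for the marks, the top 50% of each list, an overlap of at least 50% of a region, at least 2 libraries of a group in place of all, replicate numbers as a block, each naming series alone, and each replicate left out. The presence counts, the list tests and the shifts were tested on simulated data before use. In a simulation of siJunb against siControl over 77240 regions with 200 regions removed and 200 added, 200 and 200 were recovered among 554 lost and 608 gained calls, so background calls stood beside the planted ones. Planted regions were given the exact pattern that defines a call, so their full recovery was certain. It says nothing about regions missed in lists of unequal length or enrichment. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.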

Results

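By its title, the series concerns an interaction of the linker histone H1.0 with JUNB, an AP-1 transcription factor, and the identity of cells. The cells were mouse embryonic fibroblasts induced to express Mef2c, Gata4 and Tbx5, a combination used to turn fibroblasts into cardiomyocyte-like cells. MEF2C was mapped at day 1 of induction in 8 libraries, 2 under siControl, 3 under siJunb and 3 under siH1f0. H1.0, encoded by H1f0, and the heterochromatin mark H3K9me3 were mapped in 2 ground-state and 2 day 1 siControl libraries each. MEF2C lists held from 11731 peaks over 13.4 Mb (siJunb replicate 1) to 49011 peaks (siJunb replicate 2), and the widest coverage was 89.8 Mb (siH1f0 replicate 2). H1.0 lists held 32934 to 722322 peaks over 28.6 to 1109 Mb, and H3K9me3 lists held 24219 to 69439 peaks over 65.9 to 363 Mb. The 8 MEF2C lists merged into 77240 regions, of which 43575 (56.4%) occurred in 1 library and 4310 in all 8.

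Where MEF2C lay in control cells was read from the 10802 regions held by both siControl libraries. Such regions lay within 5 kb of 9 of 13 AP-1 family genes, among them Jun, Junb, Fos, Fosb, Fosl2 and Atf3, where 2.81 were expected from all protein-coding genes (odds ratio 8.16, adjusted p = 0.00164, Fisher's exact test over 21 lists). They lay next to 10 of 15 housekeeping genes such as Actb and Eef1a1 (odds ratio 7.26, adjusted exact p = 0.00158). The AP-1 excess was thus not shown to go beyond that of broadly expressed genes. Expected counts took in all protein-coding genes, since expression was not measured here. Regions also lay next to 21 of 57 clustered protocadherins, cell-adhesion genes in tandem arrays (odds ratio 2.12, adjusted exact p = 0.0379). All 21 belonged to the gamma cluster, where neighbouring genes share regions. Sensory receptor genes were nearly free of MEF2C. Regions lay next to 11 of 1110 olfactory receptors against 240 expected (odds ratio 0.0340, adjusted exact p = 3.3e-100). They lay next to 3 of 355 vomeronasal receptors against 76.8 expected (odds ratio 0.0303, adjusted exact p = 4.5e-32). Among sarcomere and contractile genes, 11 of 30 had a region, against 6.49 expected, which did not pass (adjusted exact p = 0.167). They included Actc1 (cardiac actin), Myl7 (atrial myosin light chain), Tpm1 and Ttn (titin). Fibroblast and extracellular matrix genes had 11 of 27, including Vim, Pdgfra, Thy1 and Col5a2 (5.84 expected, adjusted exact p = 0.0819). Hox genes had 15 of 39 (adjusted exact p = 0.0617) and linker histones 5 of 9 (adjusted exact p = 0.0815).

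The other lists did not pass either. Regions lay next to 5 of 21 cardiac transcription factors and natriuretic genes (Srf, Mef2a, Mef2d, Ankrd1 and Zfpm2, adjusted exact p = 0.875). They lay next to 4 of 16 calcium handling and ion channel genes (Atp2a2, Hrc, Kcnj2 and Trdn, adjusted exact p = 0.875) and 4 of 14 energy metabolism genes (Acadm, Esrra, Ppara and Ppargc1a, adjusted p = 0.727). The counts were 6 of 16 for cell cycle (adjusted exact p = 0.276), 28 of 101 for ribosomal protein (adjusted p = 0.278) and 83 of 400 for zinc finger genes (adjusted p = 0.875). Lists of other lineages had 2 of 10 smooth muscle, 1 of 14 skeletal muscle, 2 of 12 neuronal, 0 of 9 hepatocyte, 1 of 10 blood and immune and 0 of 8 endothelial genes. Their adjusted exact p-values went from 0.356 to 1. All 8 MEF2C libraries, knockdowns included, held a region next to Actc1, Myl7, Myom1, Myom2, Tpm1, Cryab, Xirp1 and Synpo2l among sarcomere genes. The AP-1 genes with a region in all 8 were Jun, Junb, Fos, Fosb, Fosl2, Atf3, Bach1 and Mafk, and the fibroblast genes were Vim, Pdgfra, Thy1, Ddr2, Col5a2, S100a4 and Ccn2. Nppa, a natriuretic peptide gene, and Ryr2, the cardiac calcium release channel, had a region in 0 of 8.

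The siJunb comparison asks how MEF2C regions differed when JUNB was targeted. Of the 10802 siControl regions, 1528 were in none of the 3 siJunb libraries, 4.18 times the 365 ± 19.4 (SD) of 100 randomised tables. In the opposite direction 198 regions were in all 3 siJunb and neither siControl library, fewer than the 414 ± 17.0 of randomised tables. These gained regions were weak, with a median within-list signal percentile of 34.4 over the libraries that held them. It was 73.8 for regions held by both siControl libraries. Lost regions lay less often near gene ends: 22.6% were within 5 kb of a gene end, against 38.0% of the 9274 siControl regions found in at least 1 siJunb library (odds ratio 0.476, p = 3.7e-33, Fisher's exact test across regions). They were also weaker in siControl, with a median within-list signal percentile of 46.6 against 70.2, and 13 of the 1659 siControl regions in the top 10% of signal were lost. Their median width was 2238 bp, against 3726.5 bp for all siControl regions. Signal and width were not matched in the test of position, so it does not set position apart from them. Leaving out siControl replicate 1 raised the lost count to 8129, siControl replicate 2 to 3182 and siJunb replicate 2 to 2864. The gained count was 1078 without siControl replicate 2, 3340 without siJunb replicate 1, 380 without siJunb replicate 2 and 568 without siJunb replicate 3. Another split of the same 5 libraries stood farther above its randomised mean. Both siControl libraries and siJunb replicate 1 held 324 regions missing from siJunb replicates 2 and 3, 6.36 times the 51.0 of randomised tables. In counts alone, siJunb replicates 2 and 3 shared 3142 regions found in none of the other 3 libraries (2935 in randomised tables). Of the 10 splits, 4, the real one included, separated at least as many regions in total, with 1726 in the real split and 3466 in the largest.

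The strongest lost region was at chromosome 17, 70962910 to 70964086, 9.88 kb from Myl12b, a regulatory myosin light chain gene. The next were at chromosome 13, 9011669 to 9012655, 15.6 kb from Gtpbp4, and at chromosome 8, 15519070 to 15520568, 372 kb from Csmd1. The others of the 10 lay within Dscam, Olfm3, Taf4b, Atrnl1 and Tnni3k, a cardiac kinase gene (chromosome 3, 154938001 to 154940484), or nearest to Npy5r and Fam174a. The strongest gained region was at chromosome 13, 116192608 to 116193102, outside any gene and 105 kb from Isl1, a cardiac progenitor factor, with maximum signals of 26, 57 and 76 in the 3 siJunb libraries. The next lay inside Slc8a3, a sodium-calcium exchanger gene (chromosome 12, 81278006 to 81279034), and others of the 10 lay within Prelid3a, Gm4924 and Lamc3 or nearest to Vmn1r2, Gm40363, Epop, Hrh1 and Abt1. Among the cardiac, fibroblast, AP-1 and linker histone lists, 3 genes had a lost region within 5 kb. They were Esrra, a nuclear receptor of energy metabolism, Col5a1, a collagen gene, and Thy1, which had other regions in all 8 libraries. Some MEF2C region lay next to Esrra in 2 of 2 siControl, 1 of 3 siJunb and 3 of 3 siH1f0 libraries and next to Col5a1 in 2 of 2, 0 of 3 and 2 of 3. For Cacna1c, the cardiac L-type calcium channel, the numbers were 2 of 2, 0 of 3 and 3 of 3, and for Twist1, a mesenchymal transcription factor, 2 of 2, 0 of 3 and 2 of 3. Neither had 1 region in both siControl libraries and no siJunb library, and both were chosen after their values were seen.

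Under siH1f0, MEF2C kept most control regions. Of the 10802 siControl regions, 192 were in none of the 3 siH1f0 libraries, 1.07 times the 179 ± 13.0 of randomised tables, and 346 regions were gained, fewer than the 618 ± 21.7 of randomised tables. The gained regions had a median within-list signal percentile of 40.3 over the libraries that held them. Of the 10 splits, 7, the real one included, separated at least as many regions in total, with 538 in the real split and 4342 in the largest. The lost ones again lay less often near gene ends, with 23.4% within 5 kb of a gene end against 36.1% of the others (odds ratio 0.543, p = 0.000249, Fisher's exact test across regions). They were weak in siControl, with a median percentile of 26.4 against 67.2, and had a median width of 1957.5 bp. As under siJunb, signal and width were not matched in the test of position. The strongest lost region was the one 372 kb from Csmd1 that was also lost under siJunb, followed by regions 3.64 kb from Tubb3, a neuronal tubulin gene, and 5.29 kb from Krt23. The others of the 10 lay within Hmcn1 and Sfi1 or nearest to Tmem135, Nkx2-6, Hrh1, Rpusd4 and 4930467E23Rik. Regions named under either knockdown were not checked for repeats or artefact signal. The strongest gained regions lay across the ends of Map3k10 (chromosome 7, 27674197 to 27675868) and Prkra (chromosome 2, 76647309 to 76650817), 31.7 kb from Cited2, in Gm13275 and in Auts2. The others of the 10 lay within Mamstr, a MEF2 co-activator gene, Podxl2 and Wipf3 or nearest to Foxn3 and Nrp1. Ldb3, a Z-disc protein gene, was the gene of the cardiac, fibroblast, AP-1 and linker histone lists with a gained region, in 0 of 2 siControl, 0 of 3 siJunb and 3 of 3 siH1f0 libraries. The gained count was 3061 without siControl replicate 2, 874 without siH1f0 replicate 1 and 1990 without siH1f0 replicate 3. The lost count was 3376 without siControl replicate 1, 1709 without siControl replicate 2 and 753 without siH1f0 replicate 2.

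**Figure D1:**
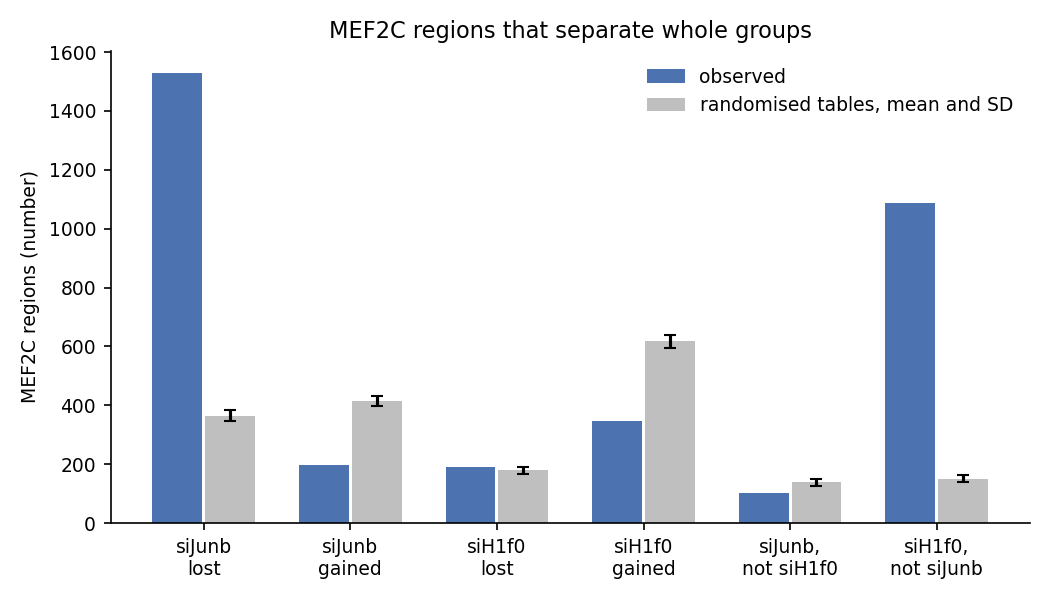
Number of MEF2C regions that separated whole groups of libraries at day 1 (blue) beside the mean and SD of 100 randomised tables (grey, error bars). The 1528 regions lost under siJunb and the 1088 held by all siH1f0 and no siJunb library lay above the randomised 365 and 151, and the 198 and 346 gained regions lay below theirs. Error bars do not show the spread between libraries. Splits that mixed the groups, not drawn here, reached 6.36 times their randomised mean for siJunb and siControl and 3.82 times for siJunb and siH1f0.

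The genes chosen in advance gave few whole-group differences. Next to Actc1, Jun, Fos, Junb and Thy1, all 8 libraries had a region. Libraries under siControl, siJunb and siH1f0 with a region next to Ttn numbered 2 of 2, 2 of 3 and 3 of 3, and next to Tnnt2 1, 1 and 2. For Col1a1 they numbered 1, 3 and 3, for Postn 1, 1 and 3 and for Fosl1 1, 1 and 2. For H1f0 itself they numbered 1, 2 and 2, for Mef2c 1, 1 and 0, for Gata4 1, 0 and 2, for Tbx5 1, 2 and 3 and for Myh6 1, 0 and 0. Reads from the transgenes and the reporter were not told apart from those of the native genes. Near gained and lost regions, 0 of 84 combinations of list and set passed the adjusted threshold (smallest adjusted p = 1, Fisher's exact test with Benjamini-Hochberg adjustment). An unadjusted p under 0.05 came up in 1, the neuronal list for regions lost under siH1f0, through Tubb3 (exact p = 0.020). Few hits were expected for most lists. For sarcomere genes, the largest cardiac list, 0.155 were expected near gained and 0.744 near lost regions under siJunb. Under siH1f0 0.325 and 0.0925 were expected. Fewer hits than expected could hardly show at such counts, so the tests do not show that these lists were unaffected. The share of sarcomere genes with a region was 56.7% ± 9.43 (SD, n = 2) in siControl, 38.9% ± 5.09 (n = 3) under siJunb and 54.4% ± 10.2 (n = 3) under siH1f0. For siJunb against siControl it gave an exact permutation p of 0.2, the smallest possible, and an adjusted p of 1 over 66 tests. The number of regions per library was 25923 ± 16655 under siJunb (n = 3), 23391 ± 9065 under siH1f0 (n = 3) and 19347 ± 8870 in siControl (n = 2). Two-sided exact permutation p-values against siControl were 1 and 0.8.

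The knockdowns were then set against each other. MEF2C occupied 1088 regions in all 3 siH1f0 and no siJunb library, 7.21 times the 151 of randomised tables, and 102 in the opposite pattern (139 in randomised tables). Splits that mixed the knockdowns also left their randomised means. The highest ratio was 3.82, for 249 regions held only by siJunb replicate 1 and siH1f0 replicates 1 and 2 (65.1 in randomised tables). The highest count was 1933, held only by siJunb replicate 2 and siH1f0 replicates 1 and 2 (1120 in randomised tables). The strongest of the 1088 lay in Tnni3k, and others lay within Pappa2, nearest to Ascc3 and Akr1e1, 3.98 kb from Lmcd1, a cardiac-expressed LIM gene, and across an end of Creb5. The 102 were led by the regions near Isl1 and in Slc8a3 and included a region 171 kb from Sox9. Of the siControl regions, siJunb replicates 1, 2 and 3 held 53.2%, 77.9% and 64.4% (65.2% ± 12.4, n = 3). The siH1f0 replicates held 90.7%, 97.1% and 73.4% (87.1% ± 12.3, n = 3). The siJunb minus siH1f0 difference was -21.9 percentage points (two-sided exact permutation p = 0.2, adjusted p = 0.2 over 8 tests).

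Within the first naming series the shares were 53.2% for siJunb and 73.4% for siH1f0, and within the second 77.9% and 64.4% for siJunb and 90.7% and 97.1% for siH1f0. With lists of equal length, chosen after seeing the data for this measure, each siJunb library held less (64.5%, 70.6% and 66.8%) than each siH1f0 library (89.4%, 91.8% and 79.5%). The exact permutation p was 0.1, the smallest possible and the rate at which chance separates 3 libraries from 3, and the adjusted p was 0.2. In the top 10% of siControl signal, siJunb libraries held 94.9% ± 2.71 and siH1f0 libraries 99.4% ± 0.471 (n = 3 each, exact permutation p = 0.1, adjusted p = 0.2). Both comparisons shared the siControl libraries. They had 15 gained regions in common, where independent sets among the 49348 regions in neither siControl library would share 1.39 and the randomised mean was 95.8 (75 to 120). They had 132 lost regions in common, where independent sets would share 27.2 and the randomised mean was 98.2 (67 to 124). The siControl libraries were not divided between the comparisons, and the randomised tables kept them shared. Against those tables the 15 lay below the range and the 132 above it. The tables did not keep the sizes of the gained and lost sets. They therefore do not say how much of the excess over independence came from sharing the siControl libraries.

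**Figure D2:**
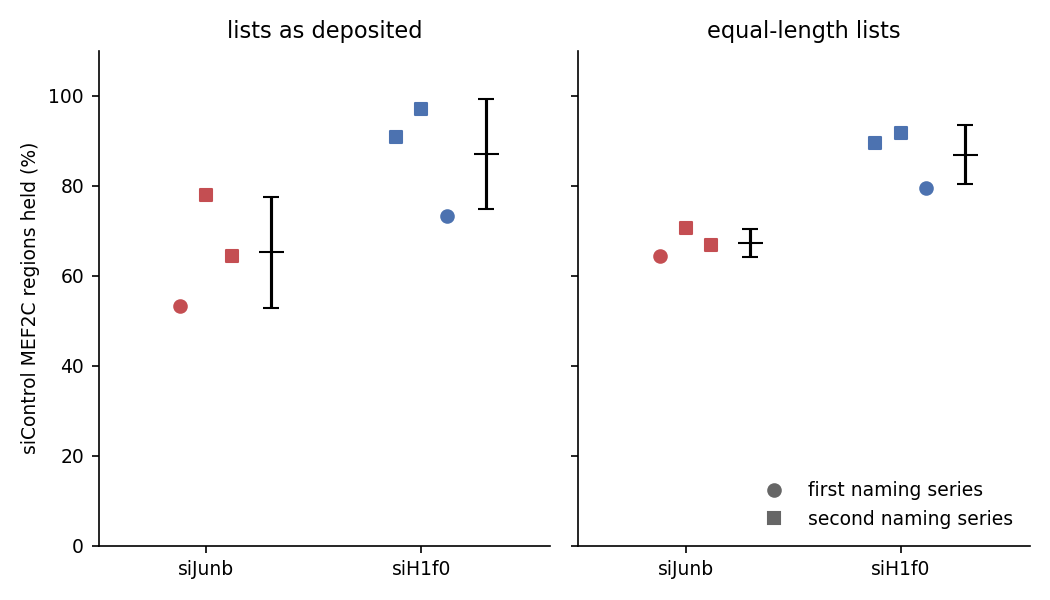
Share (%) of the regions held by both siControl libraries that each siJunb (red) and siH1f0 (blue) library also held, for lists as deposited (10802 regions) and of equal length (7657 regions), with black bars for the mean and SD of 3 libraries. Circles are the first naming series and squares the second, and in each series the siJunb points lay below the siH1f0 points.

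H1.0 was compared between ground-state cells and day 1 of induction. The labels give plating, siControl transfection and doxycycline for day 1 cells only. Differences between the states, for H1.0 and H3K9me3 alike, thus cannot be assigned to the induced factors alone. The sequence under H1.0 was 601 ± 719 Mb in the ground state and 470 ± 624 Mb at day 1 (SD, n = 2 each), with a two-sided exact permutation p of 0.667. Both naming series showed less sequence at day 1, 93.0 against 28.6 Mb in the first and 1109 against 911 Mb in the second. Sequence held by both ground-state and neither day 1 library came to 15.0 Mb and the reverse to 4.02 Mb, which was no more than the 18.8 and 4.25 Mb of a split that mixed the states. With equal covered length these were 0.511 and 1.13 Mb, so the larger side turned. Genes whose bodies were covered in both ground-state and not in both day 1 libraries included 15 at 100%, among them Nudt8, Hcrt (the hypocretin gene), 4933412E24Rik and the olfactory receptors Olfr324 and Olfr1002. In 10 of the 15 the second-series library covered the whole body in both states. Genes covered in both day 1 libraries and not in both ground-state libraries included 4 at 100%, LOC115486880 and the replication-dependent histone genes H2ac12, H3c2 and H2bc13 on chromosome 13 (H3c2 at 23752345 to 23752840). In these 4 the second-series library covered the whole body in both states, and the first-series library set the difference, going from 0% to 100%.

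Among genes chosen in advance, the body share under H1.0 in both libraries was 14.9% in the ground state and 9.26% at day 1 for Tnnt2, 9.58% and 0.939% for Myh6, 2.11% and 0.612% for Ryr2, 1.44% and 0.899% for Ttn, and 0% and 13.6% for Actc1. Junb, H1f0, Jun, Fos, Fosl1, Col1a1, Postn, Thy1, Nppa and Mef2c had 0% shared by both libraries in either state. Gata4 and Tbx5 had 0% and 1.11% or 0.458%. Such a 0% need not be absence from each library. H1f0 had 100% in the ground state and 64.02% at day 1 in the second-series libraries. Nppa had 92.31% in the first-series ground-state library. For Tnnt2, Myh6, Ryr2, Ttn and Actc1 the first-series libraries moved in the direction given. In the second-series libraries the share rose for Tnnt2 (61.03% to 76.56%), Myh6 (31.7% to 59.16%) and Ryr2 (28.19% to 34.11%). There it fell for Actc1 (100% to 64.16%) and, in the direction given, for Ttn (80.94% to 65.01%). The shares in both libraries have no error of their own, since each needs both libraries of a state.

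**Figure D3:**
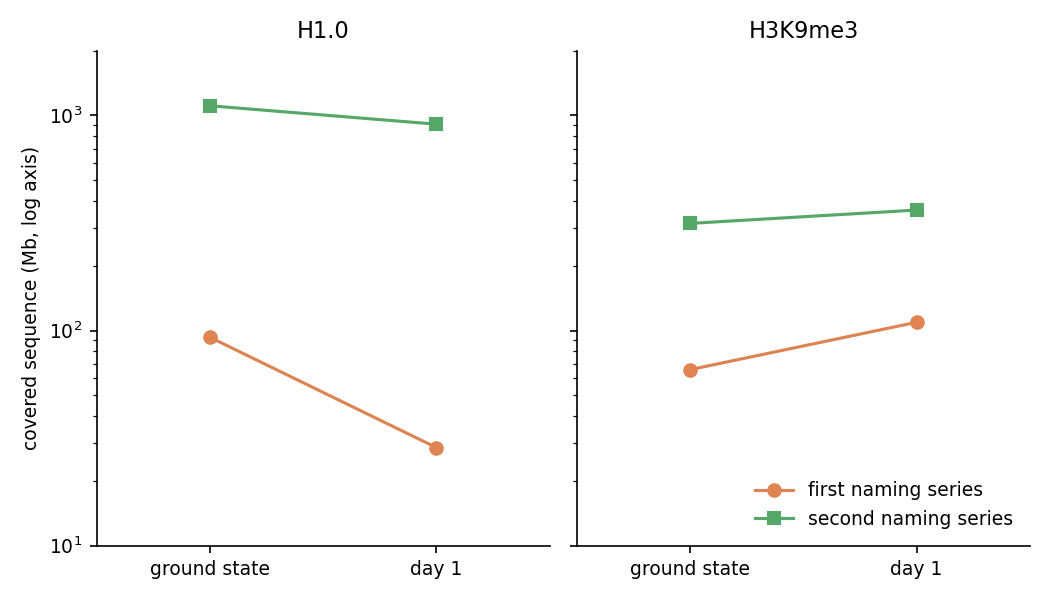
Sequence covered by the H1.0 and H3K9me3 lists (Mb, log axis) in the ground state and at day 1, with lines joining the lists of one naming series. H1.0 went from 93.0 to 28.6 Mb in the first series and from 1109 to 911 Mb in the second, and H3K9me3 from 65.9 to 109 Mb and from 315 to 363 Mb.

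H3K9me3 covered 190 ± 176 Mb in the ground state and 236 ± 180 Mb at day 1 (SD, n = 2 each), with a two-sided exact permutation p of 0.667. Coverage was larger at day 1 in both naming series, by 43.4 Mb (66.0%) in the first and 48.3 Mb (15.3%) in the second. Of the 21 gene lists, olfactory receptors had the largest difference in both naming series, with 4.45% of the gene body covered in the ground state and 8.90% at day 1 in the first series, and 19.7% and 29.7% in the second (two-sided exact permutation p = 0.667 with n = 2, adjusted p = 1 over 44 tests). Vomeronasal receptors had 2.75% and 5.07% in the first and 15.5% and 22.2% in the second series. Zinc finger genes had 11.9% and 12.4% in the first series and 21.6% and 19.9% in the second. Clustered protocadherins had 2.23% and 3.33%, then 13.9% and 10.6%, and all protein-coding genes 1.75% and 2.67%, then 6.50% and 7.10%. With equal covered length, added after seeing the data, the olfactory receptor difference was -0.205 percentage points (95% interval -1.03 to 0.704) in the first series and 4.19 (0.864 to 8.14) in the second. The vomeronasal receptor difference was then -0.408 (-1.89 to 0.512) and 0.0913 (-0.834 to 1.36).

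Sequence held by both day 1 and neither ground-state H3K9me3 library was 8.08 Mb and the reverse 1.06 Mb, while splits that mixed the states gave 4.69 and 1.51 Mb, and 140 and 0.288 Mb for the split by naming series. With equal covered length the values were 2.21 and 3.17 Mb, so the larger side turned. Genes whose whole body was covered in both day 1 libraries and no part of it in both ground-state libraries numbered 42, the longest of them Olfr1299, Nap1l5 (an imprinted nucleosome assembly gene), G6pd2, Olfr1037, Tdpoz3, Olfr1042, Olfr1020, Olfr1029, Defa24 and Olfr598. In 35 of the 42, these 10 among them, the second-series library covered the whole body in both states, so the first-series library set the difference. The opposite set held 6 at 100%, Olfr1308, Olfr1022, Olfr1019, Vmn1r215, Rnase2a and Gm9789, where again the second-series library covered the whole body in both states, followed by Olfr820, Gm7762, Olfr142 and Olfr1031. Of the genes chosen in advance, Ryr2 had 0.588% in the ground state and 4.92% at day 1 in both libraries, Ttn had 0% and 0.391%, and the other 15 had 0% in both states.

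**Figure D4:**
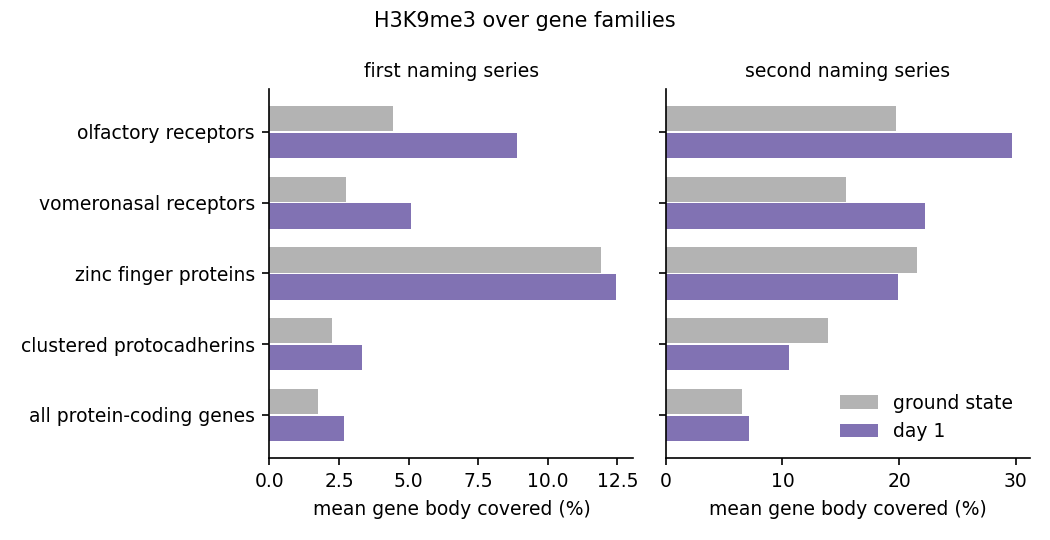
Mean share (%) of gene bodies covered by H3K9me3 in 5 gene groups, in the ground state (grey) and at day 1 (purple), for the single libraries of the first and second naming series. Olfactory receptors went from 4.45% to 8.90% and from 19.7% to 29.7%, and with equal covered length the first-series difference turned to -0.205 percentage points.

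Whether the linker histone sat in heterochromatin was read from sequence that both libraries of each mark covered. In the ground state 2.04 Mb lay under both H1.0 (53.6 Mb) and H3K9me3 (63.0 Mb), 1.40 times the mean of 100 circular shifts, and at day 1 1.12 Mb lay under both, also 1.40 times that mean. In either state 0 of 100 shifts were as large. The sequence shared by the 2 H1.0 lists was itself 1.23 times the mean of 20 shifts in the ground state and 1.69 times at day 1. Sequence in either library of each mark gave the opposite, 0.784 times in the ground state and 0.762 times at day 1. The fold also fell below 1 when the short H1.0 list was left out, 0.733 without ground-state replicate 1 and 0.812 without day 1 replicate 2, and when the short H3K9me3 list was left out, 0.839 without ground-state replicate 1 and 0.800 without day 1 replicate 1.

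MEF2C regions were set against the chromatin of cells before induction. H1.0 regions of both ground-state libraries overlapped 15.8% of the 77240 MEF2C regions, 1.81 times the 8.76% of circular shifts, and H3K9me3 regions overlapped 4.40%, 0.794 times the 5.54% of shifts. As large were 0 and 100 of 100 shifts. The H1.0 set itself was 1.23 times what shifts of the 2 ground-state lists gave (53.6 against 43.7 Mb), and the H3K9me3 set 6.61 times. Much of the H1.0 set could therefore be overlap without agreement between the 2 libraries. Regions gained under siJunb overlapped H3K9me3 in 9.09% (odds ratio 2.18 against all other regions, adjusted p = 0.00878, Fisher's exact test over 8 tests), and regions lost under siJunb in 2.23% (odds ratio 0.490, adjusted p = 1.8e-05). They overlapped H1.0 in 33.8% when gained (odds ratio 2.73, adjusted exact p = 3.7e-09) and in 11.7% when lost (odds ratio 0.702, adjusted exact p = 1.8e-05). Under siH1f0, H1.0 overlapped 21.1% of gained regions (odds ratio 1.43, adjusted exact p = 0.0153) and 15.6% of lost ones (odds ratio 0.986, adjusted exact p = 1). H3K9me3 overlapped 2.89% (odds ratio 0.646, adjusted exact p = 0.253) and 5.73% (odds ratio 1.32, adjusted p = 0.427). Against regions held by all libraries of the knockdown and by at least 1 siControl library, a background chosen after seeing the data, the H1.0 calls for gained regions ended for siJunb (odds ratio 1.20, unadjusted exact p = 0.237) and for siH1f0 (0.807, unadjusted exact p = 0.114). Against the siControl regions kept under siH1f0, those lost had an odds ratio of 0.600 for H1.0 (unadjusted exact p = 0.00968). With widths matched in these backgrounds, the H1.0 odds ratios were 1.74 for regions gained and 0.640 for regions lost under siJunb, and 1.13 and 1.17 under siH1f0, so the 0.600 turned. The H3K9me3 odds ratio for regions gained under siJunb was then 3.42, and under siH1f0 it was 1.20 for regions gained and 2.38 for regions lost. The width-matched values carry no test. For H3K9me3 at regions lost under siJunb, the odds ratio of 0.490 became 0.579 against kept siControl regions (unadjusted Fisher's exact p = 0.00170). With widths matched as well, the overlap was 2.23% against 2.39%, an odds ratio of 0.929. Other calls began under alternatives. H1.0 at regions lost under siH1f0 had an odds ratio of 0.512 with lists of equal length (adjusted exact p = 0.000819). H3K9me3 at regions gained under siH1f0 had 0.524 with either ground-state library (adjusted exact p = 0.00372) and 0.204 with an overlap of at least 50% (adjusted exact p = 0.0150). H1.0 at regions gained under siH1f0 lost its call with lists of equal length (0.804, adjusted exact p = 0.277) and with that overlap (0.803, adjusted exact p = 0.578). With either ground-state library the odds for H1.0 at regions lost under siJunb turned to 1.25 (unadjusted exact p = 0.00186), and with lists of equal length the H3K9me3 odds at regions gained under siJunb were 1.32 (unadjusted p = 0.311).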

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

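The tests in this part were chosen only after the result was seen, apart from 2 kinds. Counts with equal-length lists were planned, though their bounds were set later. The bound for H3K9me3 over olfactory receptors with equal covered length over both naming series together was set before its value was computed, and the reading of the second series by itself was added later.

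Peaks on unplaced scaffolds entered no comparison. They numbered 174 in the MEF2C, 1238 in the H1.0 and 773 in the H3K9me3 lists, on scaffolds outside the assembled chromosomes, and 44.3%, 57.3% and 46.1% of them lay on scaffolds assigned to chromosome 1. They made up 0.0846%, 0.0986% and 0.378% of all peaks, and control samples were not analysed here.

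The absence of siControl MEF2C regions from siJunb libraries, with 1528 regions in none of the 3, was weighed first. List length alone was argued against, since with equal-length lists 1197 regions were lost and the highest count in the 9 other splits was 598. A weaker enrichment in the siJunb libraries stays open and was not decided. In the second naming series the median peak maximum was 7 and 9 in siJunb replicates 2 and 3. It was 20 in siControl replicate 2 and 17 and 16 in siH1f0 replicates 1 and 2. In the first series it was 7 in siJunb replicate 1, 9 in siControl replicate 1 and 8 in siH1f0 replicate 3. Aligned depth was not given, so the lower siJunb values go with weaker enrichment without deciding it. The median siControl signal percentile of the lost regions minus that of the kept ones was -23.7 points, but regions lost under siH1f0, whose number was 1.07 times the randomised mean, gave -40.8, so such a gap also arose without an excess of lost regions and decides nothing. The 324 regions held by siJunb replicate 1 and both siControl libraries but missing from siJunb replicates 2 and 3, at 6.36 times their randomised mean, show structure among the siJunb libraries themselves. An effect of lower JUNB on MEF2C binding may add to this, but nothing here sets it apart from weaker enrichment, and knockdown was not measured here.

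The difference between siJunb and siH1f0 rested on 6 libraries, whose 10 splits are too few for a share under 0.05. In all, 1190 regions separated the groups, 2 splits gave as many, and the highest other count was 1960, for siJunb replicates 1 and 3 with siH1f0 replicate 3 against the rest, which follows the first naming series in part. With equal-length lists the values were 776 and 356.

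The H1.0 lists of the second naming series were 11.9 times as long in covered sequence as those of the first in the ground state and 31.9 times at day 1. A lower signal threshold in the long lists was argued against in units of signal, as their smallest total signal was at least 1.04 times that of the short lists, although a threshold relative to depth remains open. Greater depth of the long lists cannot be told apart from other causes, because the signal per base at shared sequence was 1.45 times as high at day 1 and just under 1.5 times in the ground state. A value of 1.5 in both states would have spoken for depth and no excess in both against it. These bounds were set with the medians of signal per base of the whole lists already seen, and replaced a test of total fragments that was not run. No biological explanation was tested, since each series held both states.

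Higher H3K9me3 over olfactory receptor genes at day 1 was weighed last. More sequence called at day 1 could account for it in the first naming series, where the difference with equal covered length was -0.205 percentage points (95% interval -1.03 to 0.704). It was argued against as the whole cause in the second series, where 4.19 points remained (0.864 to 8.14) and 56 genes were higher and 5 lower. A change common to silent gene families stays open. Vomeronasal receptors moved by 6.70 points (2.45 to 12.6) in the second series as deposited, which goes with it, and by 0.0913 (-0.834 to 1.36) with equal covered length, an interval that still meets that of olfactory receptors. In the first series they moved by 2.32 (1.17 to 3.83) as deposited and by -0.408 (-1.89 to 0.512) with equal covered length. Zinc finger genes moved by -1.63 (-2.51 to -0.676) in the second series and 0.556 (-0.247 to 1.62) in the first as deposited, but nothing here shows that they are silent. The rule for this test was changed more than once after its values were seen. Earlier forms asked for a fall over zinc finger genes, and read in the second series alone they argued against a common change. Reprogramming stays open as an untested explanation, with 1 library per state in each series. It cannot be told apart from plating, siControl transfection and doxycycline, which the labels give for day 1 cells only.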

How the results depend on the processing

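The tests of the share of siControl regions held, of gene family shares with equal covered length, and of narrower and width-matched backgrounds were chosen only after the result was seen. Of 203 alternatives over 31 results, 101 kept the direction and the side of the threshold or stayed within 1.5 times. The 0 of 84 list tests held under all 3 alternatives run, with 1 or 2 unadjusted p-values under 0.05 in each (Fisher's exact test). Few hits were expected for most lists in the main setting, so this does not show that the lists were unaffected. The siJunb minus siH1f0 difference in the share of siControl regions held was between -17.3 and -24.4 percentage points with equal-length lists, near or away from gene ends and within each naming series. By siControl signal it was -28.1 under percentile 50, -27.3 from 50 to 75, -17.6 from 75 to 90 and -4.46 above. The folds of MEF2C regions at H1.0 stayed between 1.10 and 2.65 and at H3K9me3 between 0.608 and 0.913. At 0.913, with an overlap of at least 50%, 12 of 100 shifts were as small, against 0 in the other settings. The motif alternatives were not run, because the genome sequence was not used here. The 30 M reads of the labels do not give aligned depth, so the extent of the lists, which differed by up to 31.9 times in covered sequence within a group, limits every count.

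Counts that ask for fewer libraries grow by construction. Leaving out single replicates gave 231 to 3340 regions gained and 1852 to 8129 lost under siJunb, 416 to 3061 gained and 233 to 3376 lost under siH1f0, and 1368 to 3935 differing between the knockdowns. Asking for at least 2 libraries of a group gave 3892 gained under siJunb, 2610 gained under siH1f0 and 7279 differing. Within the first and second naming series 4578 and 3470 were gained and 7170 and 8827 lost under siJunb, 7601 and 2210 gained and 4908 and 3687 lost under siH1f0, and 13289 and 6951 differed. For the rest the cause was not tested. The top 50% of each list gave 623 lost under siJunb, 81 lost under siH1f0 and 548 differing. An overlap of at least 50% gave 54 gained and 500 lost under siJunb, 92 lost under siH1f0, 659 differing and 3 gained under both. Equal-length lists gave 776 differing and 39 gained under both.

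Replicate numbers as a replicate block gave 568 regions gained under siJunb and 1990 gained under siH1f0. The region number under siH1f0 was then 7855.5 above siControl, and no other block value moved by over 1.5 times or changed direction. Against siControl the block only left out replicate 3 of the knockdown. In the other comparisons it returned the main value by construction, so it could not test pairing. Its values are counted among the alternatives above. Deviations of same-numbered libraries from their group means had correlations across regions from -0.107 to 0.167. The highest of all values was 0.241, for siControl replicate 1 and siH1f0 replicate 3, both of the first naming series. Deviations of 2 siControl libraries mirror each other, so this check could say little about pairing. The numbers were not taken to pair the samples.

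Region number against siControl ranged from -2249.5 to 14295.5 under siJunb and from -2228 to 10316 under siH1f0 with single replicates left out. It turned negative without siJunb replicate 2, and for siH1f0 without siControl replicate 1 or siH1f0 replicate 2. The day 1 minus ground-state coverage ranged from -640 to 377 Mb for H1.0 and from -81.1 to 173 Mb for H3K9me3, turning positive for H1.0 without replicate 2 of either state and negative for H3K9me3 without ground-state replicate 1 or day 1 replicate 2. H1.0 sequence lost was 0.511 Mb with equal covered length, 87.2 and 566 Mb in the first and second series and 15.6 to 561 Mb with replicates left out, and sequence gained was 1.13, 22.8, 368 and 5.30 to 348 Mb. H3K9me3 sequence lost was 3.17, 22.1, 67.9 and 1.52 to 62.8 Mb in that order, and sequence gained 2.21, 65.6, 116 and 8.58 to 114 Mb. The fold of H1.0 over H3K9me3 was 0.784 and 0.762 with either library in the ground state and at day 1, and 0.733 to 1.61 and 0.800 to 1.52 with replicates left out. With equal covered length, H3K9me3 over olfactory receptors differed by -0.205 points in the first series, and over vomeronasal receptors by -0.158 on average and -0.408 in the first series. Odds ratios for H1.0 turned to 1.25 for regions lost under siJunb with either ground-state library. They turned to 0.807 (background held by all siH1f0 and at least 1 siControl library), 0.804 (equal length) and 0.803 (overlap of at least 50%) for regions gained under siH1f0. They turned to 1.17 (width matched) and 1.35 (overlap of at least 50%) for regions lost under siH1f0. Those for H3K9me3 turned to 1.20 for regions gained (width matched) and 0.517 for regions lost (equal length) under siH1f0. In each case the cause was not tested.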

Other observations

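The test of H3K9me3 over zinc finger genes and the comparison of library pairs were chosen only after the result was seen.

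At day 1 all 8 MEF2C libraries held a region next to the linker histone genes H1f1, H1f2, H1f3, H1f5 and H1f6. Among cell cycle genes all 8 held a region next to Trp53, Cdkn1a and Pcna. Of smooth muscle genes, Cald1 and Actg2 had a region in all 8, and of skeletal muscle, neuronal, hepatocyte, blood and endothelial genes 0 did. These counts follow from the lists as deposited and carry no test of their own.

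H3K9me3 lay over zinc finger genes, many of them in repetitive clusters, at 6.80 times the share of all protein-coding genes in the ground state and 4.66 times at day 1 in the first naming series, and at 3.32 and 2.81 times in the second. With equal covered length the zinc finger share was lower at day 1 by block bootstrap in both series, with differences of -0.684 (95% interval -1.22 to -0.166) and -1.00 percentage points (-1.91 to -0.132), each from 1 library per state. Cardiac transcription factors and natriuretic genes stood at 0.0757 and 0.0196 times the share of all genes in the first series and 0.232 and 0.115 times in the second. Cell cycle and linker histone genes had 0% under H3K9me3 in all 4 libraries. H1.0 over linker histone genes stood at 1.93 and 0.990 times the share of all genes in the first series and 2.10 and 1.88 times in the second.

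Libraries of H3K9me3 shared sequence with each other at 4.97 to 12.6 times the mean of circular shifts and libraries of H1.0 at 1.23 to 4.57 times. The lowest H1.0 value was that of the 2 ground-state libraries and the highest that of the 2 first-series libraries. Such a fold is capped by the covered length of the longer list, so the values do not rank the pairs. MEF2C libraries shared a mean of 0.206 of their joint regions within siJunb (3 pairs), 0.429 within siH1f0 (3 pairs) and 0.387 within siControl (1 pair), and 0.268 between siControl and siJunb and 0.445 between siControl and siH1f0 (6 pairs each). These shares are bounded by the ratio of list lengths, which differed most among the siJunb libraries. The bound does not account for every low share. SiControl replicate 2 (25619 regions) shared 0.296 with siJunb replicate 3 (23712 regions) and 0.592 with siH1f0 replicate 1 (20990 regions).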
